A study of Homo sapiens with 56 samples.

How the data were processed

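The deposited table holds 1 FPKM value (fragments scaled by gene length and library size) for each of 58097 genes in each of 56 libraries, printed to 2 decimals, as computed by the authors. Per the submitters' processing notes, reads were aligned with Bowtie2 and quantified with RSEM on genome build hg38. Per the labels the libraries were made by RNA exome capture and sequenced as read pairs on an Illumina instrument. The annotation release is not stated. Of the gene identifiers, 57836 occur in GENCODE release 29, which was used for positions and gene types. Fragment counts were not used here, so the depth of each library is unknown and no counting error is given.

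Summed FPKM ran from 606269 to 666326 per library, and 12669 to 13896 genes had at least 1 FPKM. The 10 genes with the highest values took 4.87% to 7.32% of the sum. Libraries of a group correlated at 0.95 or more on the log2 scale across genes, and no 2 libraries had identical values. There were 15261 genes at 0 in every library, and 200 gene symbols stood on more than 1 row, which were kept apart by identifier.

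Values were transformed to log2(FPKM + 1) with no scaling between libraries. Genes with at least 1 FPKM in at least 4 libraries were tested, which left 15923. Limma 3.58.1 in R 4.3.3 fitted 14 group means to the 56 libraries, with a trend in the prior variance and without robust estimation. The comparison of genotypes under vehicle used the 8 vehicle libraries and 13212 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of the 21 comparisons, with a threshold of 0.05. Chance alone puts about 0.05 of the genes tested at unadjusted p < 0.05, so a count under that share is no sign of further changes. The vehicle libraries carry no exposure time and served as the reference for both 4 h and 16 h. Fold changes at low FPKM are understated by the added 1.

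The comparisons, tests, filter, gene lists, gene-naming rule and alternatives were set before the data were examined. Another fit, also set then, gave each line its own level, as a fixed block, and left 36 residual degrees of freedom instead of 42. The labels give each line's name, and the values bear out that lines pair the libraries. After group means were removed, libraries of the same line correlated across genes at 0.43 to 0.82, and libraries of different lines at -0.43 to -0.02. The fit with the block is therefore the more sensitive for changes within a line, and its counts of genes stand beside those without it. It rests on few lines, and when only the groups in a comparison were fitted the block left few degrees of freedom. Applying the naming rule to the blocked fit, and leaving lines out of it, were chosen after seeing the data.

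Gene lists were written beforehand from general knowledge, with 16 lists of pathways and 5 lists of 6 markers of other cell types. Some lists share genes and are not independent. BCL2, BCL2L1 and MCL1 are both STAT5 targets and anti-apoptotic genes. BCL2L11, BMF, IL7R, NFKBIA and BIRC3 are glucocorticoid receptor targets and also stand on the pro-apoptotic, IL-7 receptor or NF-kB lists. They were tested with camera in limma on the same fit, at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. The estimated correlation comes from the same libraries and is the stricter of the settings. Of 336 pairs of list and comparison 70 passed at the preset correlation and 17 at the estimated one. Counts adjusted over the list alone use the Benjamini-Hochberg method on the members only. Overlaps are set beside the product of the 2 counts over the genes tested, as independent lists would give.

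Genes were named by a fixed rule, and 1 gene that passed it is not reported here. A set of 20 focus genes could be named in every comparison, together with up to 10 passing genes per direction with the largest change that moved alike in all 4 lines, and up to 4 passing members per list with the smallest adjusted p. For STAT5A and STAT5B the mean over the 7 libraries of each line was compared between genotypes by an exact permutation test over all 70 arrangements. Paralog pairs such as STAT5A and STAT5B may exchange reads in quantification, so their levels are uncertain. The departure from additivity is the effect of IL-7 in the presence of dexamethasone minus its effect in vehicle.

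The method was first run on simulated FPKM values with known changes in 200 genes. For IL-7 added to dexamethasone at 16 h the fit without a block recovered 38%, 90%, 92% and 98% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, and with the block 90%, 96%, 100% and 100%. For the genotypes under vehicle it recovered 12%, 80%, 88% and 100%. False calls made up 0% without the block and 4% with it. The simulated changes were equal in all lines of a group, had independent normal residuals and were placed only in genes with higher levels. These shares therefore need not hold for low genes or for changes that differ between lines.

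Other splits of the lines served as a check on each count without the block. With the block they were run only for dexamethasone within a genotype and for added IL-7 at 16 h, in scramble lines and as the difference between genotypes. For a comparison within a genotype condition labels were exchanged within lines, since lines pair the libraries, which gives 8 splits. The splits that exchange libraries between lines were also run without the block, sorted by how many lines have a library in both groups. For a comparison of genotypes the 8 lines were divided anew in 35 ways, and for the departure from additivity 100 orders of the labels were drawn. Outlying lines were sought with Dixon's ratio at the 95% level in groups of 4. Calculations outside R used Python with numpy, pandas and matplotlib for the plots.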

Results

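The data cover CCRF-CEM, a human T-cell acute lymphoblastic leukaemia line, in 56 RNA libraries. They come from 4 lines made with a scramble guide (S1, S2, S18, S19) and 4 lines labelled as STAT5A and STAT5B knockouts (AB1, AB10, AB17, AB22). Each line was given vehicle, or dexamethasone, IL-7 or both for 4 h or 16 h, and 1 library was made per line and condition, so each of the 14 groups holds 4 libraries. Dexamethasone is a glucocorticoid that kills many T-lineage leukaemia cells, and IL-7 is a cytokine that signals through JAK1, JAK3 and STAT5 and keeps thymocytes alive. The design therefore asks what each agent does to transcripts, what IL-7 adds in cells already given dexamethasone, and which of these changes need STAT5. Values are FPKM computed by the authors from exome-capture RNA libraries. The number of fragments per library is unknown, and changes are given on the scale of log2(FPKM + 1), which understates those of low genes.

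STAT5A and STAT5B transcripts were still measured in every line labelled knockout, so the RNA level alone does not show the loss. Over the 28 knockout libraries STAT5B lay between 31.7 and 43.6 FPKM, against 42.2 to 64.8 in the 28 scramble libraries. The line means differed by -0.47 on the log2 scale (SD 0.04 and 0.16 between lines; exact permutation p = 0.029, the smallest that 4 against 4 lines allow). STAT5A ranged from 15.8 to 83.2 FPKM in knockout lines and from 20.3 to 77.9 in scramble lines (difference -0.47, exact permutation p = 0.37), and AB10 had more STAT5A in vehicle than any scramble line. An edited gene can still be transcribed, and STAT5A and STAT5B are close paralogs whose reads may be shared, so both levels are uncertain. Whatever is said of STAT5 here therefore rests on the label of the lines.

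**Figure D1:**
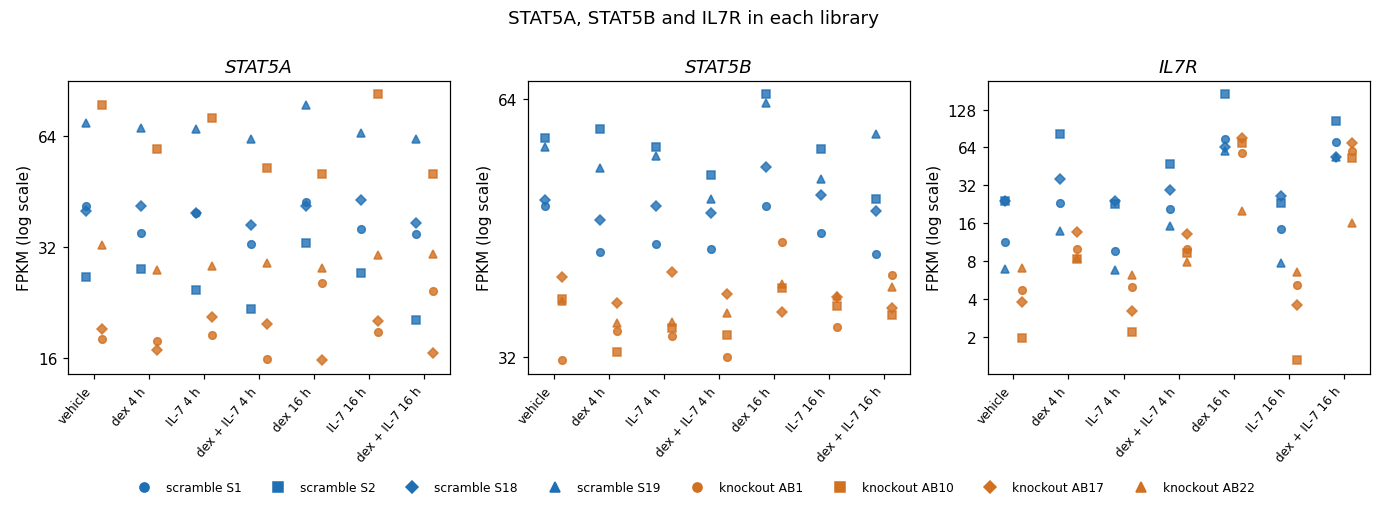
FPKM of STAT5A, STAT5B and IL7R in each of the 56 libraries, by condition and genotype. Each point is 1 library; marker shape gives the line.

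Under vehicle, scramble and knockout lines differed in no gene that passed the test. Limma called 0 of 13212 genes, with 301 at unadjusted p < 0.05, and leaving out AB1 or S2 gave 1. The gene of most interest for this design was IL7R, which encodes the IL-7 receptor alpha chain. It averaged 4.36 FPKM (SD 2.10) in knockout lines and 16.6 (SD 8.82) in scramble lines, a log2 difference of -1.64 (SE 0.42, adjusted p = 1). Of 16 IL-7 receptor signalling components 0 passed over all genes, and over the list alone 2 were lower and 0 higher in knockout lines (camera adjusted p = 0.37, 0.93 estimated). BCL2, which blocks cell death, stood at 6.16 (SD 1.38) and 6.30 (SD 0.403) FPKM. The list of MYC and ribosome biogenesis genes was higher in knockout lines at a preset correlation between genes (median 0.07, camera adjusted p = 0.0073) but not with an estimated one (0.93), and the mitochondrial transcripts behaved alike (median 0.18; 0.022 and 0.93). In simulated data a change of 1 on the log2 scale was recovered for 80% of genes in this comparison and a change of 0.5 for 12%, so differences between the genotypes could be missed, larger ones too where lines vary as they do for IL7R.

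At 4 h dexamethasone raised a small set of genes in scramble lines, several of them listed glucocorticoid receptor targets. TSC22D3, the leucine zipper gene also called GILZ, rose from 0.938 to 62.9 FPKM (log2 change 4.87, SE 0.46, adjusted p = 1.8e-09). The PI3K inhibitor PIK3IP1 rose by 3.03 (SE 0.31, 6.6e-09), the TNF family ligand TNFSF8 by 2.93 (SE 0.43, 4.6e-05) and the receptor co-chaperone FKBP5 by 2.09 (SE 0.22, 1.1e-08). The growth arrest gene BTG1 rose by 1.87 (adjusted p = 0.00084; 0.12 without S19) and the activation marker CD69 by 1.47 (0.021; 0.46 without S19). NR3C1, the glucocorticoid receptor itself, rose by 1.38 (SE 0.20, 4.6e-05). BCL2L11, which encodes the death factor BIM, was already up by 0.95 (SE 0.20, 0.039), although leaving out S19 took that to 1. BTG1, CD69 and BCL2L11 were each higher in 4 of 4 lines. With the line as a block their adjusted p was 1e-11, 2.1e-08 and 0.00032. Of 23 measured glucocorticoid receptor targets 7 rose and 0 fell, or 14 when adjusted over the list alone (median 0.95; camera adjusted p = 2.6e-58, and 8.6e-13 with an estimated correlation).

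In all, limma called 13 genes in scramble lines at 4 h, every one of them higher. A fit with the line as a block called 415, 175 higher and 240 lower, and after median rescaling of the libraries that split turned to 212 and 151, so its balance is not fixed. Leaving out S19 or S1 gave 8 genes without the block, and leaving out S2 gave 166 with it. The MYC and ribosome biogenesis list was slightly lower at the preset correlation (median -0.10, adjusted p = 0.0085; 0.86 estimated), as was cholesterol synthesis (median -0.12, 0.015; 0.86 estimated).

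After 16 h the same receptor targets were higher still, and a broad programme of growth genes had fallen in scramble lines. Glucocorticoid receptor targets rose in 20 of 23 cases (21 over the list alone; median 2.06, camera adjusted p = 5.9e-10 with an estimated correlation). TSC22D3 reached a log2 change of 6.04 (SE 0.46, adjusted p = 4.1e-13), FKBP5 3.10 (SE 0.22, 2.7e-14) and NR3C1 1.86 (SE 0.20, 6.9e-09). Genes for ribosome biogenesis and other MYC targets fell in 16 of 20 cases (19 over the list alone; median -0.64, 6e-26, and 0.0029 estimated). Among them were the spermidine synthase SRM (-0.88, SE 0.12, 1.5e-06) and the polyamine enzyme ODC1 (-0.97, SE 0.17, 0.00016). Outside the list the nucleolar factor LYAR fell as well (-1.07, SE 0.13, 4.5e-08). MYC itself, which drives such genes, fell by 1.32 (adjusted p = 0.01; 0.1 without S1).

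Dexamethasone also raised parts of the IL-7 receptor pathway in scramble lines at 16 h. IL7R rose from 16.6 (SD 8.82) to 92.3 (SD 51.6) FPKM (log2 change 2.43, SE 0.49, adjusted p = 0.00069), and JAK1, the kinase bound to that receptor, by 1.14 (SE 0.21, 0.00023). As a list the 16 receptor pathway components were not called (3 rose, 0 fell, also 3 and 0 over the list alone; camera adjusted p = 0.22). In the blocked fit members moved both ways, 6 higher and 4 lower. Death genes rose too, in 3 of 8 pro-apoptotic BCL2 family members, the same 3 over the list alone (adjusted p = 0.019), a call lost with an estimated correlation (0.23) or with the line as a block (0.4). BCL2L11 rose by 2.06 (SE 0.20, 6.4e-10) and its relative BMF by 2.86 (SE 0.36, 2.8e-07). PMAIP1, another member, was lower in 4 of 4 lines, called only with the line as a block (-0.98, block SE 0.09, adjusted p = 6.8e-12; 0.33 without it). BCL2 was not called (-0.08, SE 0.19, adjusted p = 0.9), and BCL2L1, which encodes BCL-XL, was lower only with the line as a block (-0.43, block SE 0.09, adjusted p = 0.00024; 0.1 without the block).

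Transcripts of NOTCH targets, sterol synthesis and the cell cycle moved down as lists with less certainty. NOTCH targets fell in 2 of 9 cases (3 over the list alone; 0.0089, 0.29 estimated), led by HES1 (-1.96, SE 0.32, 3.8e-05), a direct NOTCH target, and NOTCH1 itself (-0.90, adjusted p = 0.0086; 0.081 without S1). Cholesterol synthesis and uptake genes fell in 6 of 18 cases (11 over the list alone; 9.2e-09, 0.23 estimated), among them the squalene synthase FDFT1 (-0.75, 0.0045; 0.055 without S1). In the blocked fit 16 of the 18 fell, including HMGCS1 (-1.0, adjusted p = 1.5e-06). Cell cycle genes fell in 3 of 25 cases (6 over the list alone; 0.0009, 0.29 estimated), for instance the replication helicase subunit MCM7 (-0.46, 0.016; 0.18 without S19). In the blocked fit members of 2 of these lists moved both ways. NOTCH targets had 2 higher and 5 lower, and cell cycle genes 4 higher and 13 lower. Of 10 mitochondrial transcripts 2 rose (6 over the list alone; 0.00063, 0.29 estimated), MT-ATP6 by 0.53 (adjusted p = 0.028; 0.15 without S1). The NF-kB targets BIRC3 (2.45, SE 0.36, 4.1e-06) and NFKBIA (1.54, SE 0.25, 3.9e-05) rose while their list of 13 did not (adjusted p = 0.74). Interferon response genes rose in 3 of 18 cases (5 rose and 1 fell over the list alone) without a call for the list (0.26), and the 29 T-lineage genes moved both ways (0.8). Histone genes rose in 1 of 9 cases (3 over the list alone; 0.033, 0.29 estimated). The stress and unfolded protein response list was lower (median -0.30, 0.025, 0.45 estimated) and glycolysis was not called (0.059).

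For scramble lines at 16 h limma called 1256 genes, 629 higher and 627 lower. The blocked fit called 6251, 3799 higher and 2452 lower. Without the block, leaving out S2 gave 612, S18 674, S1 692 and S19 745.

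Lines labelled knockout answered dexamethasone much as scramble lines did. At 4 h TSC22D3 rose by 4.90 (SE 0.46, adjusted p = 7.4e-10) and NR3C1 by 1.36 (SE 0.20, 4.8e-05), and again 7 of 23 receptor targets rose (17 over the list alone; 9e-68, 7.4e-14 estimated). SOCS1, which restrains JAK signalling, rose by 1.63 (0.0046; 0.34 without AB10), and the mTOR inhibitor DDIT4 by 2.39 (0.0069; 0.23 without AB10). Scramble lines raised both too at 4 h, SOCS1 by 1.06 and DDIT4 by 1.73. Those rises were called only with the line as a block (0.0042 and 6.7e-05; 0.52 and 0.35 without it). At 16 h SOCS1 rose by 2.68 in scramble lines (SE 0.31, 2.9e-08). BCL2L11 was 0.89 higher in knockout lines at 4 h (SE 0.20, adjusted p = 0.066), a call only with the line as a block (0.00056). The pro-apoptotic list was higher at the preset correlation (median 0.31, camera adjusted p = 0.0017; 0.083 estimated). MYC and ribosome biogenesis (median -0.16, 9.4e-06; 0.46 estimated) and cholesterol synthesis (median -0.12, 0.024; 0.83 estimated) were lower there. Limma called 16 genes, all higher, and 534 with the line as a block, 207 higher and 327 lower. Leaving out AB10 gave 10 without the block, and leaving out AB17 gave 224 with it.

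The 16 h response of knockout lines shared most of these parts. Receptor targets rose in 19 of 23 cases (20 over the list alone; 6e-10 estimated), with TSC22D3 at 5.82 (SE 0.46, adjusted p = 1.5e-12). IL7R rose from 4.36 (SD 2.10) to 55.7 (SD 24.8) FPKM, a log2 change of 3.34 (SE 0.49, 3.9e-06). BCL2L11 rose by 2.23 (SE 0.20, 9.7e-11) and BMF by 2.21 (SE 0.36, 2.8e-05), but the pro-apoptotic list was not called here (2 of 8 rose, also 2 over the list alone; 0.063, 0.35 estimated). MYC and ribosome biogenesis genes fell in 19 of 20 cases (20 over the list alone; 6.4e-29, 0.0015 estimated), including SRM (-1.11, SE 0.12, 6.1e-09), and MYC fell by 1.47 (SE 0.34, 0.0031). HES1 fell by 2.21 (SE 0.32, 3.2e-06) and NOTCH1 by 1.03 (SE 0.23, 0.0019), with 3 of 9 NOTCH targets down (3 over the list alone; 0.012, 0.35 estimated). In the blocked fit 2 of these 9 rose and 5 fell. Mitochondrial transcripts rose in 3 of 10 cases (6 over the list alone; 0.00052, 0.35 estimated).

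Limma called 1519 genes in these lines, 761 higher and 758 lower, and 6569 with the line as a block, 3898 higher and 2671 lower. Leaving out AB1 gave 795 without the block, AB17 876 and AB10 996. Of the genes that rose at 16 h, 485 did so in both genotypes where independent lists would share 30.1, and of those that fell 544 did, against 29.8. At 4 h the genotypes shared 12 risen genes against 0.0131. Under the block the 16 h overlaps were 2950 (930 for independent lists) and 2100 (411), and those at 4 h 115 (2.28) and 132 (4.93). Across 15923 genes the 16 h changes of the 2 genotypes correlated at 0.84, and the 4 h changes at 0.31.

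For no gene did limma call a difference between the genotypes in the dexamethasone response. At 4 h it called 0 genes with 184 at unadjusted p < 0.05 (0 with the line as a block, 840 unadjusted), and at 16 h again 0 with 64 (0 and 472). The counts without the block lie under the share of 0.05 that chance gives, as the spread then holds differences between lines. A count of 0 without the block therefore carries little weight. TSC22D3 differed by 0.03 (SE 0.66) at 4 h and -0.22 (SE 0.66) at 16 h, BCL2L11 by -0.06 (SE 0.29) and 0.17 (SE 0.29), each with adjusted p = 1. The SE in this paragraph are from the fit without the block, so they too hold differences between lines. The rise of IL7R at 16 h was 0.90 larger in knockout lines (SE 0.69, adjusted p = 1), with 0.49 without AB10, 0.56 without S18 and 1.55 without AB22. The MYC and ribosome biogenesis list fell slightly further in knockout lines at the preset correlation (median -0.11, 0.02), but not with an estimated one (0.97).

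**Figure D2:**
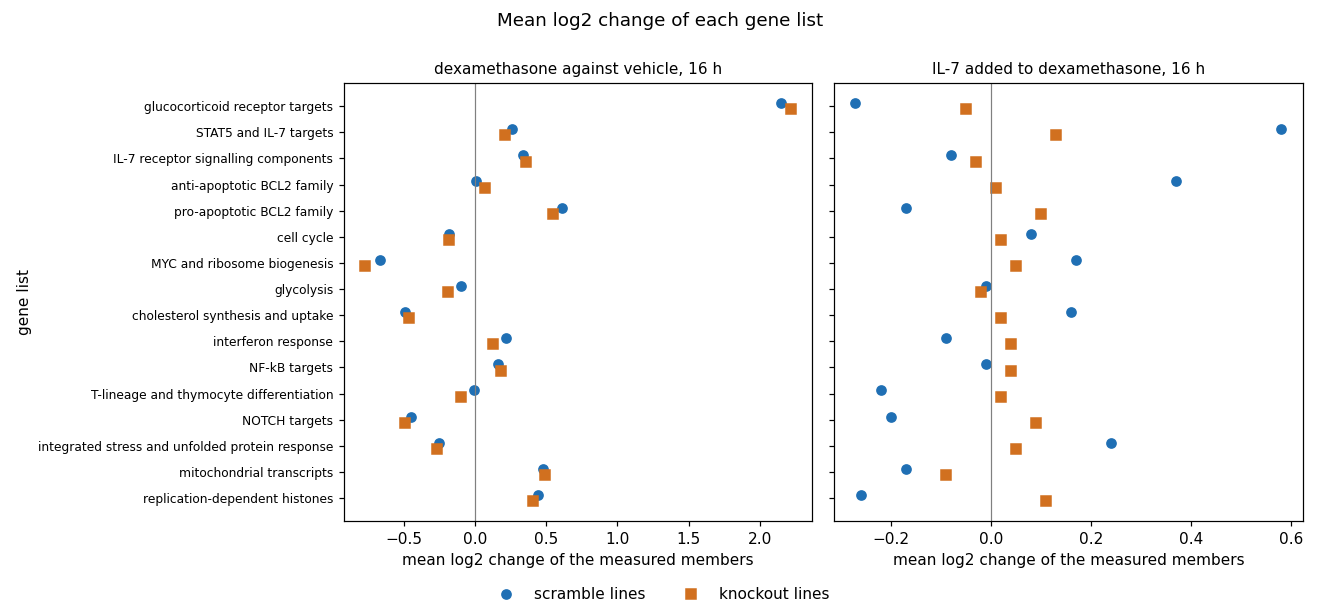
Mean log2 change over the measured members of 16 gene lists, in scramble and knockout lines, for dexamethasone against vehicle and for IL-7 added to dexamethasone, both at 16 h. Each point is the mean over the 4 lines of a genotype; no error is drawn.

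IL-7 given alone raised STAT5 target genes in scramble lines. At 4 h the list of 18 STAT5 and IL-7 targets was higher (median 0.14, camera adjusted p = 7.2e-09, 4.4e-05 estimated), with 0 members past the threshold over all genes and 1 over the list alone. CISH, a feedback inhibitor that STAT5 induces directly, stood 1.43 higher (SE 0.35, adjusted p = 1) and passed only with the line as a block (0.0055; 0.094 without S1). At 16 h CISH was the 1 called gene, up from 1.80 (SD 0.334) to 11.2 (SD 8.45) FPKM (log2 change 1.89, SE 0.35, 0.037), a call lost on leaving out S1 (0.99, at a change of 1.93) or any of 5 other lines, while the change ran from 1.49 to 2.14. The STAT5 list was again higher (median 0.20, 2.2e-17, 2.8e-08 estimated; 1 member rose, 3 over the list alone). BCL2 was not called with IL-7 alone (0.22, SE 0.19, adjusted p = 1), nor was BCL2L1, which stood 0.42 higher (SE 0.16, adjusted p = 1; 0.062 with the line as a block) in 4 of 4 lines. The anti-apoptotic BCL2 family was higher at the preset correlation (median 0.02, mean 0.13; 0.029) but not at the estimated one (0.059), with 0 members past the threshold over all genes or over the list alone, and 1 over the list alone with the block. Glycolysis genes were higher at both times at the preset correlation (medians 0.10 and 0.13; 0.0005 and 5.6e-08) but not at the estimated one (0.64 and 0.2).

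At 4 h limma called 0 genes for IL-7 alone in scramble lines, with 80 at unadjusted p < 0.05, and 3 with the line as a block (13 without S19, 0 without S1). At 16 h it called 1, and 10 with the line as a block (2 without S18, 3 without S1, 14 at most). Among those 10 were ENPEP, a peptidase of early lymphoid cells (2.72, adjusted p = 0.021; 0.33 without S1), the feedback inhibitor SOCS2 (1.27, 0.0065; 0.28 without S1) and the potassium channel gene KCNJ11 (1.12, 0.00017).

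In lines labelled knockout IL-7 alone moved no gene past the test. Limma called 0 genes at 4 h and 0 at 16 h, with 89 and 59 at unadjusted p < 0.05 (0 and 0 with the line as a block, 526 and 237 unadjusted). No list passed without the block, and with it glycolysis did at 16 h at the preset correlation (0.018; 0.91 estimated). CISH differed by -0.10 (SE 0.35, adjusted p = 1) at 4 h and 0.03 (SE 0.35, adjusted p = 1) at 16 h. Tested directly, the STAT5 list responded less in knockout than scramble lines at 4 h (median difference -0.21, 1.5e-06, 0.00055 estimated) and at 16 h (median -0.16, 4.4e-09, 3.6e-05 estimated). For single genes limma called 0 at both times, with 65 and 53 at unadjusted p < 0.05. Blocking by line, it called 0 at 4 h (402 unadjusted) and 1 at 16 h, CISH (-1.86, block SE 0.33, adjusted p = 0.026; 0.64 without AB17, and 1 without the block). CISH at 4 h differed by -1.53 (SE 0.49, adjusted p = 1).

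When IL-7 was added to dexamethasone for 16 h, scramble lines raised the survival genes BCL2 and BCL2L1. BCL2 rose from 5.93 (SD 0.306) to 16.7 (SD 6.50) FPKM, a log2 change of 1.27 (SE 0.19, adjusted p = 0.00034), in all 4 lines. BCL2 lies on chromosome 18 between 63123346 and 63320128 in hg38, by the GENCODE annotation. BCL2L1 rose by 0.81 (SE 0.16, 0.037), from 47.6 (SD 3.05) to 84.9 (SD 13.5) FPKM. CISH rose by 2.77 (SE 0.35, 6.9e-06), ENPEP by 4.38 (SE 0.77, 0.0044) and SEC31B, which encodes a coat protein of vesicles leaving the endoplasmic reticulum, by 1.5 (SE 0.30, 0.037). Without a block these were the only 5 genes, and leaving out single lines ended the calls of all but CISH. Without S1 the changes were 1.23 for BCL2 (adjusted p = 0.075), 0.80 for BCL2L1 (0.48) and 4.63 for ENPEP (0.1), and without S2 the change of SEC31B was 1.42 (0.67) and that of ENPEP 3.25. Line S2 had 341 FPKM of ENPEP with both agents, and its change there was 7.77, against 2.73 to 3.63 in the other lines. In the blocked fit all 5 stayed past the threshold whichever line was left out, the highest adjusted p being 1.2e-06 for BCL2, 6.2e-05 for BCL2L1, 9.2e-08 for CISH, 7.2e-05 for ENPEP and 5.7e-05 for SEC31B.

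**Figure D3:**
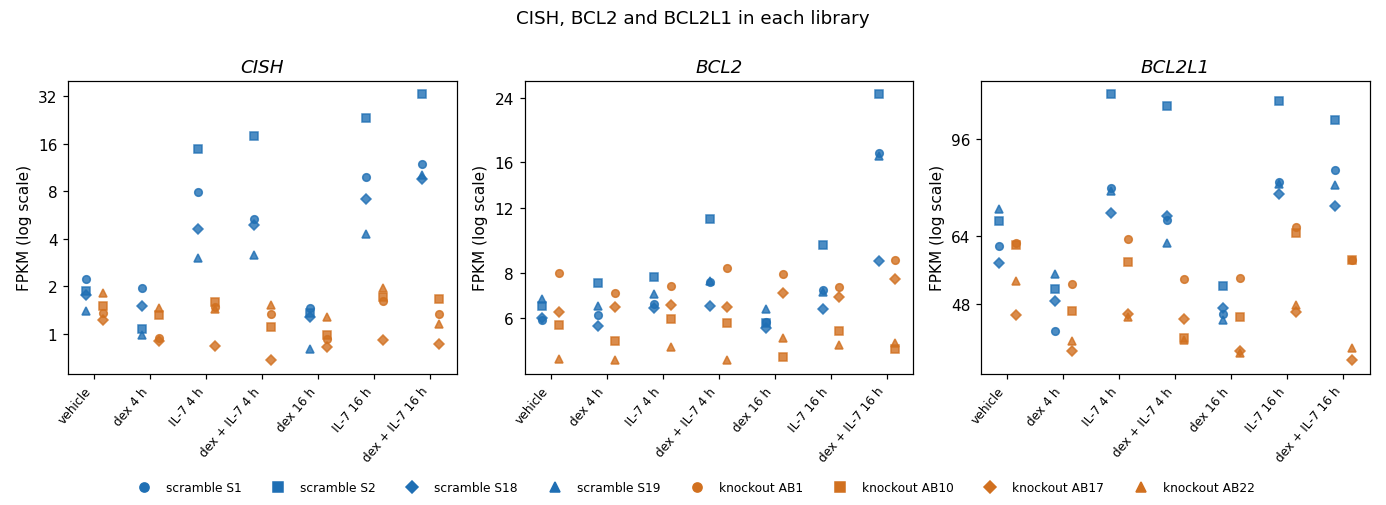
FPKM of CISH, BCL2 and BCL2L1 in each of the 56 libraries, by condition and genotype. Each point is 1 library; marker shape gives the line.

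The wider response to added IL-7 in scramble lines included STAT5 targets. STAT5 and IL-7 targets rose in 3 of 18 cases (5 over the list alone; median 0.34, adjusted p = 6.4e-11, 5.9e-06 estimated). Anti-apoptotic BCL2 family members rose in 2 of 5 cases (2 over the list alone; mean 0.37, median -0.02, 4e-05, 0.00039 estimated), so the mean reflects BCL2 and BCL2L1. With the line as a block the feedback inhibitor SOCS2 rose by 1.64 (adjusted p = 1.1e-05), the survival kinase PIM1 by 0.95 (6.2e-05) and the secretory regulator XBP1 by 1.19 (1.9e-06), where without it their adjusted p was 1, 0.86 and 1. XBP1 rose by 2.09 in S2 and by 0.78 to 0.99 in the other lines. The blocked fit takes its spread from all 14 groups, so these p-values do not measure how this response varies between lines. BCL2L11 and IL7R, both raised by dexamethasone, were lower in 4 of 4 lines but not called (-0.23, SE 0.20 and -0.30, SE 0.49; adjusted p = 1 for both), and without S2 they stood at -0.10 and -0.17. The receptor target list was lower at the preset correlation (median -0.25, 0.0012; 0.1 estimated) and the MYC and ribosome biogenesis list higher (median 0.21, 1.4e-07; 0.19 estimated), with 0 members past the threshold over all genes or over the list alone. Under the block 7 of those 20 MYC and ribosome genes rose.

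Limma called 5 genes for IL-7 added to dexamethasone at 16 h in scramble lines, all higher, with 612 at unadjusted p < 0.05. Blocking by line, it called 993, 602 higher and 391 lower. Leaving out S2 brought that to 64 and leaving out S18 to 516, so most of the wider count hangs on S2, the line in which CISH rose most (3.84). Without the block, leaving out S1 or S2 gave 1 and leaving out AB1 gave 8. When only the 8 libraries of this comparison were fitted, limma called 0 genes with or without the block. A simulated log2 change of 1 was recovered for 90% of genes here without the block and 96% with it. Those simulated changes were equal in all lines, which the real ones were not, so these shares need not apply to them.

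At 4 h the addition of IL-7 raised the STAT5 list in scramble lines (median 0.18, 3e-06, 0.00079 estimated), with 0 members past the threshold over all genes and 2 over the list alone. Limma called 0 genes, with 188 at unadjusted p < 0.05, and 6 with the line as a block, all higher (23 without S19, 3 without S2). These included CISH (1.64, adjusted p = 0.0003) and BCL2L1 (0.61, 0.0005), whose adjusted p without the block was 0.39 and 1.

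In lines labelled knockout the survival genes gave no called response to added IL-7. At 16 h BCL2 stood 0.06 higher (SE 0.19), BCL2L1 0.10 (SE 0.16) and CISH 0.16 (SE 0.35), each with adjusted p = 1. The STAT5 list was slightly higher at the preset correlation (median 0.10, 0.021; 0.13 estimated, and 0.037 estimated with the line as a block), with 0 members past the threshold over all genes or over the list alone. Limma called 0 genes at 16 h, with 81 at unadjusted p < 0.05, and 1 with the line as a block, the non-coding SRD5A3-AS1 (-0.46, adjusted p = 0.025; 0.7 without AB1). At 4 h it called 0 with 98 at unadjusted p < 0.05 (0 and 346 with the line as a block), and CISH differed by 0.00 (SE 0.35, adjusted p = 1).

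Tested directly at 16 h, the answer to added IL-7 was weaker in knockout than scramble lines for STAT5 targets and for the anti-apoptotic genes. The STAT5 list differed by a median of -0.20 (adjusted p = 0.00016, 0.0052 estimated; 0 members past the threshold over all genes, 4 over the list alone). The anti-apoptotic list differed by a mean of -0.35 and a median of -0.13 (0.0018, 0.0052 estimated; 0 over all genes, 2 over the list alone). BCL2, BCL2L1 and MCL1 are on both lists, so these are not separate results. For single genes limma called 0, with 363 at unadjusted p < 0.05, CISH coming closest (-2.61, SE 0.49, adjusted p = 0.057). With the line as a block it called 32, of which 26 had a negative difference of knockout minus scramble lines and 6 a positive one. These included CISH (2e-05), BCL2 (-1.20, block SE 0.16, 2.3e-05) and SEC31B (-1.49, block SE 0.24, 0.0012), which kept their calls whichever line was left out.

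Other genes in that set lost their call when a line was left out. Without AB17 BCL2L1 (-0.71, adjusted p = 0.0055) stood at -0.65 (0.081) and SOCS2 (-1.55, 0.024) at -1.52 (0.15), so these differences changed little. ENPEP (-4.19, 0.005) stood at -4.05 without AB22 (0.063) and at -3.06 without S2. XBP1 (-0.93, 0.048) and the T-cell regulator GATA3 (0.54, 0.047) were smaller without S2, at -0.62 (0.29) and 0.41 (0.46). The count itself ran from 7, without AB17 or AB22, to 63 without S19, and was 0 when only the groups in the comparison were fitted. At 4 h the STAT5 list again responded less in knockout lines (median -0.17, 0.00078, 0.017 estimated; 0 members past the threshold over all genes, 1 over the list alone), while limma called 0 genes with 139 at unadjusted p < 0.05 (0 and 640 with the line as a block). CISH differed there by -1.64 (SE 0.49, adjusted p = 1).

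**Figure D4:**
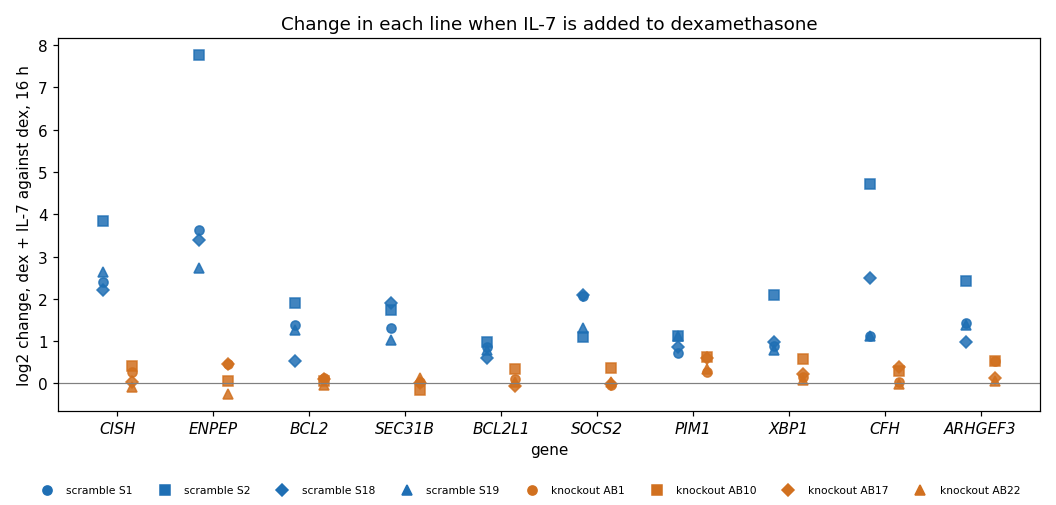
Log2 change of 10 genes in each line when IL-7 is added to dexamethasone for 16 h. Each point is 1 line; the genes were chosen from those that passed the test in scramble lines with or without the line as a block.

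Of BCL2, CISH and BCL2L1, only BCL2 passed for a rise with the 2 agents together above their sum, and only with the line as a block. In scramble lines at 16 h its departure from additivity was 1.05 (SE 0.27, adjusted p = 1; 0.00098 with the line as a block, 0.058 on leaving out S19). CISH (0.88, SE 0.49) and BCL2L1 (0.40, SE 0.23) departed less (adjusted p = 1 for both, 0.39 and 0.34 with the line as a block). The anti-apoptotic list departed upwards in its mean of 0.24, with a median of 0 (adjusted p = 0.01, 0.046 estimated; 0 members over all genes, 1 over the list alone). Blocking by line changed those values to 0.021 and 0.26. Limma called 0 genes at 16 h, with 160 at unadjusted p < 0.05, and 7 with the line as a block, all higher (2 without S19). Another of these was RGPD1, one of a family of near-identical nuclear pore genes (1.32, 0.022; 0.13 at 1.37 without S1, and 0.80 without S2), whose reads may be shared between copies. At 4 h it called 0 with 116 at unadjusted p < 0.05 (0 and 581 with the line as a block).

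Markers of other cell types gave little sign of foreign cells in the cultures. Of the B cell, myeloid, NK, erythroid and fibroblast markers only CD79A, CD79B and NKG7 had medians above 1 FPKM (17.9, 7.49 and 11.5). These genes can be transcribed in T-lineage leukaemia itself. Mitochondrial transcripts made up 3.45% to 7.46% of each library's summed FPKM and moved with the dexamethasone groups at 16 h by a median of 0.50 on the log2 scale in scramble lines and 0.53 in knockout lines, beside the fall of growth genes in the same libraries.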

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

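The splits of the lines and the test on nuclear RNAs were set before their results were seen, whereas the tests on the 32 genes, the scaling test on mitochondrial transcripts and the limit to splits that part every line were chosen after. Within a genotype only 8 splits give every line a library in both groups, as the real labels do, too few for a share under 0.05. For dexamethasone the real labels gave 13 genes (highest other split 0) at 4 h and 1256 (0) at 16 h in scramble lines, and 16 (0) and 1519 (0) in knockout lines. For IL-7 alone in scramble lines at 16 h they gave 1 (0), a call lost in 6 of the 8 fits that leave out a line, and for IL-7 added to dexamethasone there 5 (1). In the blocked fit the real labels gave 415 (highest other 1) and 6251 (825) in scramble lines and 534 (1) and 6569 (1526) in knockout lines for dexamethasone, and 993 (9) for added IL-7 at 16 h. In each of these 1 of the 8 splits, the real one, gave as many. Blocked counts for IL-7 alone, for added IL-7 at 4 h and in knockout lines, and for the departure from additivity were not set against other splits. Splits that leave both libraries of some lines on 1 side gave up to 319 for dexamethasone at 16 h in knockout lines, and for added IL-7 up to 293 at 16 h and 11 at 4 h in knockout lines and 18 at 16 h in scramble lines. The counts of 293, 11 and 18 set whole lines against each other, so differences between lines can enter them, which was not tested.

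Where limma called 0 genes, every split gave as many, so nothing is added to those counts. Counts at unadjusted p < 0.05 are given with each comparison, and those without the block lie under the share of 0.05 that chance gives. Within a genotype that was 8 of 8 splits, too few for a share under 0.05, with a highest other of 1 for IL-7 added at 4 h in scramble lines and 0 elsewhere. For comparisons of genotypes it was 35 of 35, with a highest other of 4 under vehicle, 2 for the dexamethasone difference at 16 h and 0 for the rest, so chance is not excluded there. For the departure from additivity it was 100 of 100, with a highest other of 550 at 16 h and 16 at 4 h. Those splits mix libraries with and without dexamethasone, a structure of the samples whose own effect can enter the count.

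The answer to IL-7 on top of dexamethasone at 16 h differed between the genotypes. Blocked by line, 32 genes differed, while without the block 0 did. With the block 1 of 35 splits of the 8 lines, the real one, gave as many, and the highest other split gave 0. That is the smallest share that 35 splits allow, so chance is made less likely for that count but is not excluded. Log2 differences of knockout minus scramble lines were -2.61 for CISH, -1.20 for BCL2, -0.71 for BCL2L1, -1.55 for SOCS2, -4.19 for ENPEP, -1.49 for SEC31B, -0.93 for XBP1 and 0.54 for GATA3. Differences of list means were -0.44 for STAT5 targets and -0.35 for the anti-apoptotic genes (median -0.13), lists that share BCL2, BCL2L1 and MCL1.

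Technical readings of the 32 genes were tested. Without S2, the strongest scramble line, the blocked fit still called 13 of them, so the calls of those 13 do not need S2. All 32 kept their direction whichever line was left out. That says little, since they were picked for this difference in the same lines. ENPEP went from -4.19 to -3.06 without S2, and without AB17 or AB22 the blocked fit called 7. Library scaling is argued against, since 28 were called after median rescaling. With only the libraries of the 4 groups in the comparison the blocked fit called 0 genes, so the calls need the spread estimated from all 56 libraries. A lower IL7R transcript level in knockout lines could leave less receptor for IL-7. With that level after 16 h of dexamethasone as a covariate over the 8 lines, the genotype difference kept a median share of 0.823 (quartiles 0.743 and 0.903). At that time AB10 and AB17, with 69.3 and 75.3 FPKM of IL7R, moved CISH by 0.42 and 0.03, where S1, with 75.3, moved it by 2.39. Mean IL7R was then 55.7 FPKM in knockout and 92.3 in scramble lines. The gap was wider under vehicle (4.36 and 16.6) and after 4 h of dexamethasone (10.1 and 38.5). Some lines overlapped, however. Under vehicle S19 had 6.89 FPKM and AB22 6.99, and after 4 h of dexamethasone S19 had 13.98 and AB17 13.66. Added IL-7 at 16 h moved CISH by 2.63 in S19, -0.08 in AB22 and 0.03 in AB17. In these lines a like early level did not go with a like answer of CISH, but only 1 scramble line is matched. The earlier levels were not used as a covariate, so a lower receptor level early in the exposure remains open for other lines and genes. Receptor protein was not measured, differences between edited lines other than STAT5 were not tested, and need for STAT5 is thus a hypothesis found and tested on the same data.

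Mitochondrial transcripts were higher after 16 h of dexamethasone in all 8 lines, by 0.32 to 0.70 on the log2 scale. Library scaling is argued against, since a share of 0.962 of the mean rise was left after median rescaling, in each line between 0.32 and 0.69. Loss of cytoplasmic RNA from damaged cells could also raise them and would raise RNAs held in the nucleus. Of these MALAT1 was higher by 0.46 (SE 0.09) and NEAT1 by 0.45 (SE 0.07), each in 8 of 8 lines, and KCNQ1OT1 by 0.04 (SE 0.01) at a mean of 0.169 FPKM. By the rule set beforehand damage would have needed 0.5 in each and regulation none. At 0.169 FPKM, with 1 added before the log, KCNQ1OT1 could hardly reach 0.5, so the rule could not have come out for damage. MALAT1 and NEAT1 rose within the range of the mitochondrial rise, so damage remains open and the 2 readings cannot be told apart.

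Smaller differences between the genotypes were tested as well. CISH responded less to IL-7 alone at 16 h in knockout lines (-1.86), the 1 gene called there with the line as a block. The STAT5 list responded less to IL-7 alone at 4 h (mean -0.33) and 16 h (-0.38) and to added IL-7 at 4 h (-0.31).

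Single lines stood apart from the other 3 in 14 of 199 groups of 4 values, where chance gives about 1 in 20. The groups were the changes of each named gene over the lines of a genotype, and the FPKM of STAT5A, STAT5B, IL7R, CISH, BCL2, BCL2L1, TSC22D3 and ENPEP in each of the 14 groups of libraries. Line S2 accounts for 10 of them, so they do not spread evenly over lines. It had 169 FPKM of IL7R after 16 h of dexamethasone, 113 of BCL2L1 with IL-7 at 16 h and 110 with both agents at 4 h, 32.8 and 17.8 of CISH with both agents at 16 h and 4 h, and 341 and 96.6 of ENPEP there. Its changes with added IL-7 stood apart for CISH at 4 h (3.19), XBP1 at 16 h (2.09) and TCF7 at 16 h (-0.99). AB10 had high TSC22D3 at 4 h with dexamethasone (132 FPKM) and with both agents (127). In S18 the 4 h rise of CD69 was low (1.16), and in S19 the departure of CISH from additivity at 16 h was high (1.49).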

How the results depend on the processing

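The block as an alternative was planned, while leaving lines out of the blocked fit, or changing its pseudocount, scaling or groups, was chosen after seeing the results. With the line as a replicate block the counts for dexamethasone went from 13 to 415 and from 16 to 534 at 4 h, and from 1256 to 6251 and 1519 to 6569 at 16 h, in scramble and knockout lines. For IL-7 alone they went from 0 to 3 (4 h) and 1 to 10 (16 h) in scramble lines, and from 0 to 1 for the difference between genotypes at 16 h. For IL-7 added to dexamethasone they went from 0 to 6 (4 h) and 5 to 993 (16 h) in scramble lines, 0 to 1 in knockout lines at 16 h, 0 to 32 for the difference at 16 h and 0 to 7 for the departure from additivity at 16 h. The overlaps of dexamethasone calls went from 12 and 0 to 115 and 132 at 4 h and from 485 and 544 to 2950 and 2100 at 16 h. Fitting only the groups in the contrast gave 4 and 4 (dexamethasone, 4 h), 678 and 439 (16 h), 1 and 0 (IL-7 alone, 4 h and 16 h, scramble) and 0 (added IL-7, 16 h, scramble). Without the filter 1 gene was called for IL-7 alone at 4 h in either genotype and at 16 h in knockout lines, for added IL-7 at 16 h in knockout lines and its difference, and for the departure from additivity at 16 h. With a pseudocount of 0.1 added IL-7 at 16 h gave 2, and its difference 1. Of list calls, 70 at the preset correlation, 17 passed at an estimated one, 95 passed with the block (18 with the block at an estimated correlation) and 69 after rescaling. Leaving out each line in turn gave 8 to 16 and 10 to 17 genes for dexamethasone at 4 h, 612 to 1370 and 795 to 1550 at 16 h, 0 to 1 for IL-7 alone at 16 h in scramble lines, 1 to 8 for added IL-7 at 16 h and 0 to 1 for its difference, and 0 to 1 under vehicle. For STAT5A and STAT5B it gave -0.84 to -0.23 and -0.53 to -0.42. Within the blocked fit, fitting only the groups in the contrast gave 42 and 216 (dexamethasone, 4 h), 3928 (16 h, scramble), and 0 for each other count with IL-7, the pseudocount of 0.1 gave 7 for IL-7 alone at 4 h and 2 for its difference at 16 h, and leaving out each line gave 166 to 404 and 224 to 631 (dexamethasone, 4 h), 0 to 13 and 2 to 14 (IL-7 alone, 4 h and 16 h, scramble), 0 to 4 (its difference, 16 h), 3 to 23 and 64 to 996 (added IL-7, 4 h and 16 h, scramble), 0 to 1 (knockout, 16 h), 7 to 63 (difference, 16 h) and 2 to 8 (departure, 16 h). Among the genes named in the text no call changed sign. With the block 33 gained a call and 0 lost one, and median rescaling changed 0 calls. Fitting only the groups in the contrast lost 21 calls and gained 3, leaving out the filter lost 9 and gained 0, the pseudocount of 0.1 lost 3 and gained 1, and over the fits that leave out a line 63 calls were lost and 7 gained.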

Other observations

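The list tests and the block were set beforehand, while naming genes from the blocked fit and leaving lines out of it were chosen after the results were seen. Genes of T-cell development moved apart after 16 h of dexamethasone in scramble lines, and with the line as a block 10 of 29 rose and 8 fell (11 and 9 over the list alone). LEF1, a WNT pathway factor of early thymocytes, rose by 1.10 (block SE 0.10, adjusted p = 2.2e-11), and the coreceptor gene CD8A by 1.0 (block SE 0.12, 5.1e-09). The recombinase gene RAG1 fell by 1.56 (block SE 0.28, 2.6e-05) and the T-cell factor BCL11B by 0.64 (block SE 0.09, 9.3e-08). Each moved alike in 4 of 4 scramble lines. Knockout lines gave 1.22 for LEF1 (1.3e-12), 0.95 for CD8A (1.2e-08), -2.14 for RAG1 (8e-08) and -0.61 for BCL11B (2.4e-07). Of these calls, without the block BCL11B passed in scramble lines (0.027; 0.16 without S19) and knockout lines (0.034; 0.13 without AB22) and LEF1 in knockout lines (0.043; 0.15 without AB17), and the list passed in neither genotype (0.8 and 0.52).

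Added IL-7 lowered part of this programme in scramble lines at 16 h. In the blocked fit 0 of the 29 genes rose and 4 fell (0 and 7 over the list alone; camera adjusted p = 8.4e-07, 0.035 estimated), against 0.017 and 0.44 without it. The T-cell factors GATA3 (-0.42, adjusted p = 0.0026) and TCF7 (-0.41, 0.023) fell, and both were smaller and lost their calls without S2 (-0.30, 0.2 and -0.21, 0.57). STAT5B itself was lower by 0.22 (0.021; without S2 by 0.16, 0.43).

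The proapoptotic gene PMAIP1 fell by 0.98 in scramble lines after 16 h of dexamethasone with the line as a block (block SE 0.09, adjusted p = 6.8e-12; 0.33 without it), while BCL2L11 and BMF rose, so the death genes did not move as 1 group.

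Across 15923 genes, most of them not called, changes with added IL-7 at 16 h correlated between the genotypes at -0.15, and those of IL-7 alone at -0.01, against 0.84 for dexamethasone. Single genes may still share part of the response, since PIM1 stood 0.45 higher with added IL-7 in knockout lines, in 4 of 4 lines, although it was not called (SE 0.32, adjusted p = 1 with or without the block).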
